A study of Mus musculus with 4 samples.

How the data were processed

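Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 acetylated at lysine 9 (H3K9ac), a mark found at active promoters, in mouse bone marrow-derived myeloid-derived suppressor cells (MDSC). Per the labels, the cells had been made senescent in vitro and were kept under a condition named CM, an abbreviation that the labels do not expand, with or without romidepsin, an inhibitor of histone deacetylases. The series held 4 samples, an immunoprecipitated and an input library for each of the 2 conditions. Files of the 2 immunoprecipitated libraries were used. The 2 input libraries were not analysed here. Per the labels' protocols, chromatin was crosslinked with formaldehyde, sonicated, and precipitated with an antibody against acetylated H3K9, and libraries were sequenced as single-end reads.

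Per the submitters' processing notes, Bowtie2 (version 2.4.4), MACS2 (version 2.2.7.1) and deepTools (version 3.5.1) were used with the mouse genome build mm10. The settings, the filters on reads, and whether the input served as control for peak calling were not given in the sources used here. Each file was a list of broad peaks for 1 library. For each peak, the authors' list gave a position, a score, a fold enrichment over background as a ratio, and the −log10 of a p-value and of a q-value. All these values were those of the authors' peak caller and were averages over the whole broad region, so that a wide peak can hold a higher summit than its fold shows. They were used to describe, rank and filter peaks within a list. The number of reads per library was not given in the sources used here, so the depth behind each list is unknown, and a deeper library yields more, weaker and wider peaks at the same q-value.

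Peak positions were taken as deposited and written with a first base numbered 1. Genes were taken from a RefSeq table of GRCm38.p6, the assembly that mm10 represents, which gave the start and end of 21887 protein-coding genes without strand, exons or untranslated regions. The transcription start site could not be told from the other end of a gene. The windows planned around start sites before the data were examined were therefore replaced by windows of 1 kb on either side of both annotated ends of a gene, called gene ends in the text. A gene was counted as having a peak where a gene end window overlapped a peak by at least 1 bp, and the strongest such peak by fold was used for its values. A peak at a gene end may belong to a neighbouring gene, and neighbours sharing the peak of a named gene are given in the text. Exonic and intronic positions were not analysed here. Remaining peaks were split into those elsewhere in a gene and those outside genes.

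Peaks of the 2 lists were called shared where they overlapped by at least 1 bp. Random overlap was measured over 100 placements of the peaks on their own chromosomes. Shares were given with exact Clopper-Pearson intervals at 95% confidence, which cover counting error only. With 1 library per condition no test between conditions was run, and no difference has a replicate check. For 20 gene lists, fixed before any peak position was seen, the number of genes with a peak was set beside 10000 random lists of the same size matched on gene length in 10 strata. The percentiles describe these libraries only. Matching on CpG content had been planned and was replaced by gene length, since no genome sequence was used here. Of 362 listed genes 360 were matched, and Ahsp and Mx1 were not. Genes with near-identical copies (Bcl2a1a, Bcl2a1b, Bcl2a1d, Hba-a1, Hbb-bt, Ly6c2, Ly6g and Oas1a) are uncertain, because short reads could be shared among copies.

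Genes were named by a rule fixed before the data were examined. The rule took 10 genes always named, for each list the member with the highest fold among genes with a peak in romidepsin only, in both, and in CM only, the 5 genes with the highest fold in each condition, and the 3 widest peaks of each condition. Genes named outside this rule were listed members, genes that made up a small count, genes on chromosome Y with a peak, and neighbours sharing a peak, and were chosen after their values were seen.

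Alternatives covered thresholds on −log10 q (2, 5 and 10) and on fold (2, 3 and 5), merging of peaks closer than 1 kb, chromosomes 1 to 19 and X, other overlap rules, windows of 500 bp and 2.5 kb, equal numbers of strongest peaks, and random lists without matching. Random lists matched on fold, on length, or on both for the romidepsin peak, windows over whole genes, and backgrounds of genes without a CM peak were added after the data had been seen. Comparisons of fold between the 2 lists, at pairs of peaks of similar length and over the gene lists, were also tried and left out, because the folds rest on different backgrounds. Background pileup was estimated for each list from the relation of fold to −log10 p with a pseudocount of 1. In lists simulated with a background of 0.7, 1, 2, 4 and 6 the estimate was 0.9, 1.15, 2.15, 4.2 and 6.2, so it lies too high, and most so at low background. Overlaps and percentiles were also tested on simulated data. Calculations were made in Python (version 3.11.15) with numpy (version 2.4.6), pandas (version 2.3.3), scipy (version 1.17.1) and matplotlib (version 3.10.9).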

Results

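H3K9ac was mapped in senescent mouse MDSC, immature myeloid cells that restrain T cells, under the CM condition and under CM with romidepsin, a histone deacetylase inhibitor. Each condition was represented by 1 immunoprecipitated library, so the values stand side by side without replicate error and without a test between conditions. Read depth is unknown. The comparison addressed where H3K9ac peaks lay with and without the inhibitor.

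Peaks were called at many more places with romidepsin. The CM list held 16419 peaks over 23.0 Mb and the romidepsin list 103336 peaks over 200.4 Mb, which was 6.29-fold more peaks and 8.70-fold more covered sequence. The fold enrichment in the authors' lists had a median of 5.04 in CM and 2.64 with romidepsin. The excess depended on the threshold. Among peaks with a fold of at least 5, the romidepsin list held 0.0109 times as many peaks as the CM list and covered 0.0203 times as much sequence. At a fold of at least 3 the ratio of peak numbers was 1.69, and at a −log10 q of at least 5 and 10 it was 1.92 and 2.69. The same fold did not carry the same evidence in both lists: at a fold of 3 to 3.5 the median −log10 p was 3.59 in CM and 5.51 with romidepsin.

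**Figure D1:**
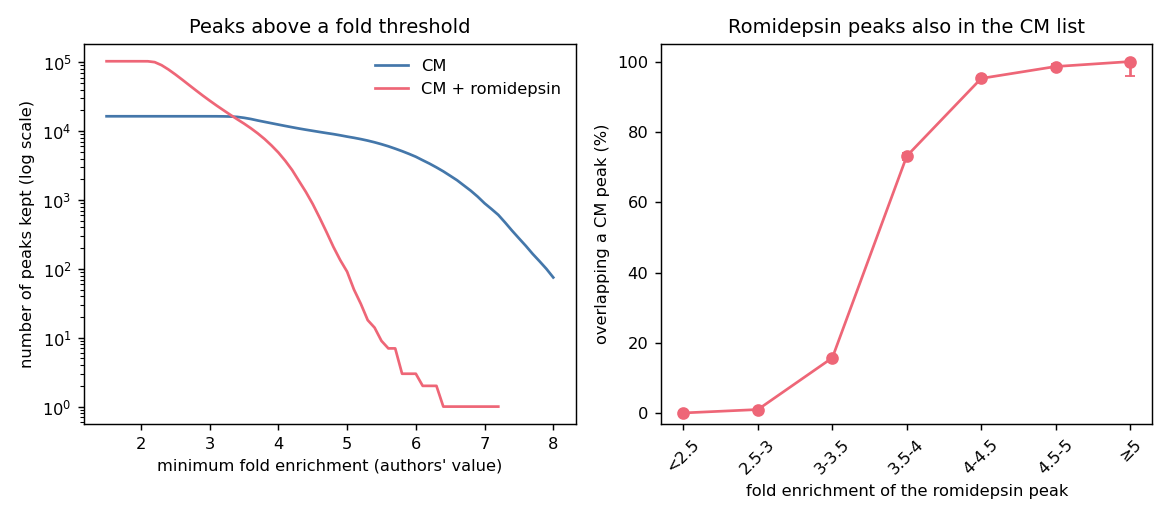
Left, number of peaks (log scale) at or above each minimum fold enrichment in the CM list and in the romidepsin list. Right, share of romidepsin peaks that overlapped a CM peak in each range of fold, with exact 95% intervals, which rose from 0.106% under a fold of 2.5 to 100% at a fold of 5 or more.

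Nearly every CM peak overlapped a romidepsin peak, and 97.9% of all CM peaks lay wholly inside one. Of the 16419 CM peaks, 16399 (99.9%, interval 99.8 to 99.9) overlapped a romidepsin peak, against 12.4% ± 0.264 (SD over 100 random placements). The remaining 20 CM peaks were short, with a median length of 454 bp. In the other direction 13312 of the romidepsin peaks (12.9%, interval 12.7 to 13.1) overlapped a CM peak, against 2.13% at random, and 90024 did not. Of these 90024 peaks, 36.4% lay within 10 kb of a CM peak, against 11.2% at random. With equal numbers of strongest peaks, 71.8% of the romidepsin peaks overlapped a CM peak and 90.2% of the CM peaks overlapped a romidepsin peak. In this setting all 16419 CM peaks were kept, and only the romidepsin list was cut, by −log10 q.

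Regions acetylated in both conditions were listed as wider domains with romidepsin. Of the 16399 shared CM peaks, 16371 had a wider romidepsin partner, taken as the longest overlapping peak. Since 97.9% of all CM peaks lay wholly inside a romidepsin peak, their partners could not be shorter. The median length was 1122 bp in CM and 5781 bp in the partner, with a median ratio of 4.37 (interquartile range 2.82 to 8.84). A romidepsin peak over several CM peaks was counted for each. Counted once each, the shared romidepsin peaks had a median length of 4865.5 bp. Peaks longer than 10 kb numbered 7 in CM and 2335 with romidepsin. The 3 widest CM peaks covered Mcl1, an anti-apoptotic BCL2 family member (chromosome 3, 95657383 to 95669099, 11.7 kb), Vmp1, an autophagy gene (chromosome 11, 86577559 to 86588892, 11.3 kb), and Psap, which encodes the precursor of the lysosomal saposins (chromosome 10, 60277045 to 60288005, 10961 bp). With romidepsin the peak at Mcl1 ran from 95623257 to 95682064 over 58.8 kb and also took in Ensa and Adamtsl4, where CM had 9 separate peaks. The other widest romidepsin peaks lay over Cyth1 (chromosome 11, 118190247 to 118251420, 61.2 kb) and Capzb, which encodes an actin capping subunit (chromosome 4, 139186594 to 139244827, 58.2 kb). Read depth, which is unknown here, also sets how wide a peak is called.

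**Figure D2:**
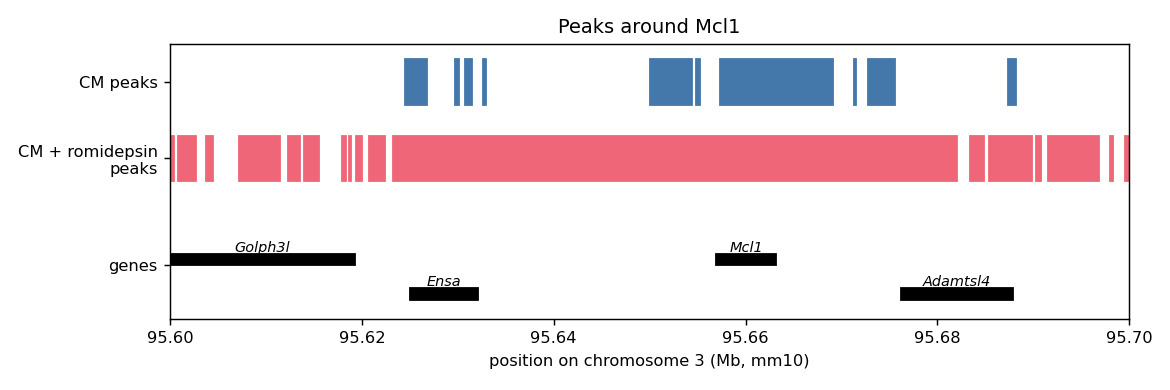
Peaks of the CM list and of the romidepsin list and protein-coding genes around Mcl1 on chromosome 3 (position in Mb, mm10). The romidepsin peak of 58.8 kb spans 9 CM peaks.

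CM peaks were concentrated at gene ends, and the additional romidepsin peaks were so to a far smaller extent. In CM, 59.9% of the peaks (interval 59.1 to 60.6) lay at gene ends, 26.4% elsewhere in genes and 13.7% outside genes. With romidepsin, 16.6% (interval 16.4 to 16.8) lay at gene ends, 52.4% elsewhere in genes and 31.0% outside genes. Random placement gave 5.22% and 5.68% at gene ends. Romidepsin peaks shared with CM lay at gene ends in 71.7% of cases and those without a CM peak in 8.44%. Their median lengths were 4865.5 and 806 bp, and a longer peak meets a gene end window more often. Random placement was not run for these sets separately. The romidepsin share was 58.6% with equal numbers of strongest peaks.

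**Figure D3:**
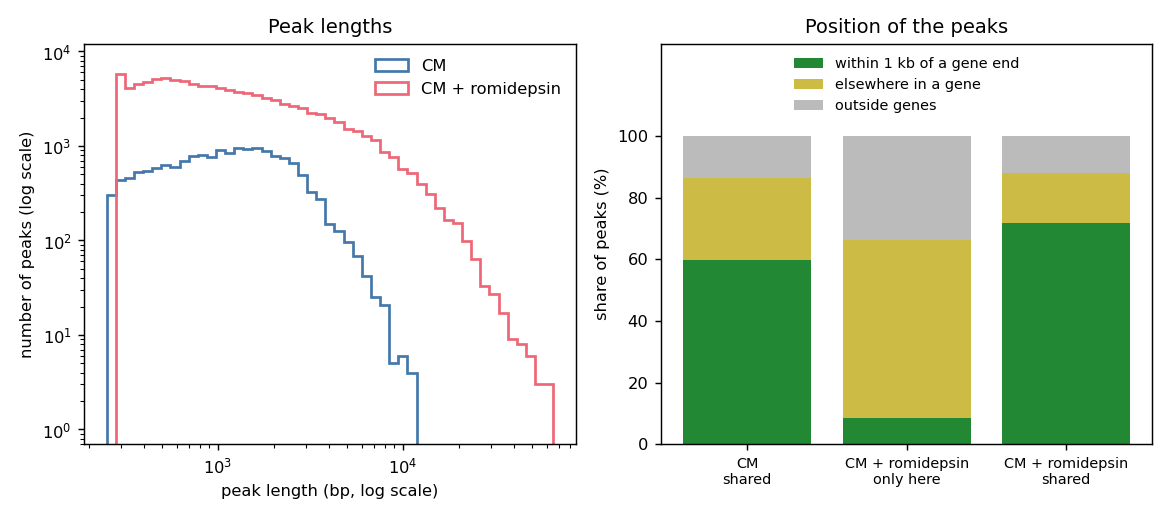
Left, distribution of peak length (bp, log scale) in both lists, with the number of peaks on a log scale. Right, share of peaks within 1 kb of a gene end, elsewhere in a gene and outside genes, for CM peaks shared with romidepsin (59.9% at gene ends), romidepsin peaks without a CM peak (8.44%) and romidepsin peaks shared with CM (71.7%).

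Of 21887 protein-coding genes, 10680 had a gene end peak in both lists, 3288 in the romidepsin list only, 1 in the CM list only (Zfp973, named after its value was seen) and 7918 in neither. At the 10680 shared genes the median fold was 5.80 in CM and 3.97 with romidepsin, each within its own list. The fold was lower with romidepsin at 10364 of these genes (97.0%). The strongest peak was taken in each list separately, so the folds of a gene can come from different peaks, also at opposite ends. Because the folds rest on different backgrounds, the pairs of folds given for single genes do not measure a loss or gain of H3K9ac. Genes with a peak in the romidepsin list only had a median fold of 3.02. Among equal numbers of strongest peaks, 1040 genes had a peak with romidepsin only and 565 in CM only. The highest folds at gene ends were found in CM at Hjurp, a histone chaperone of the centromere (10.3), Larp4b (9.25), Polr2c, an RNA polymerase II subunit (9.20), Ier5 (9.08) and Wdr70 (8.77), and with romidepsin at H60b, a ligand of the NKG2D receptor (6.07), Hectd4 (5.78), Rnf7 (5.78), Gemin5 (5.75) and Pcx, which encodes pyruvate carboxylase (5.73). All these genes had a peak in both lists. Hjurp stood apart: with romidepsin its fold of 3.57 had a −log10 q of 18.2, against 3.53 and 5.20 at Polr2c. Its fold thus did not carry the same evidence as a like fold elsewhere, and the reason was not tested.

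**Figure D4:**
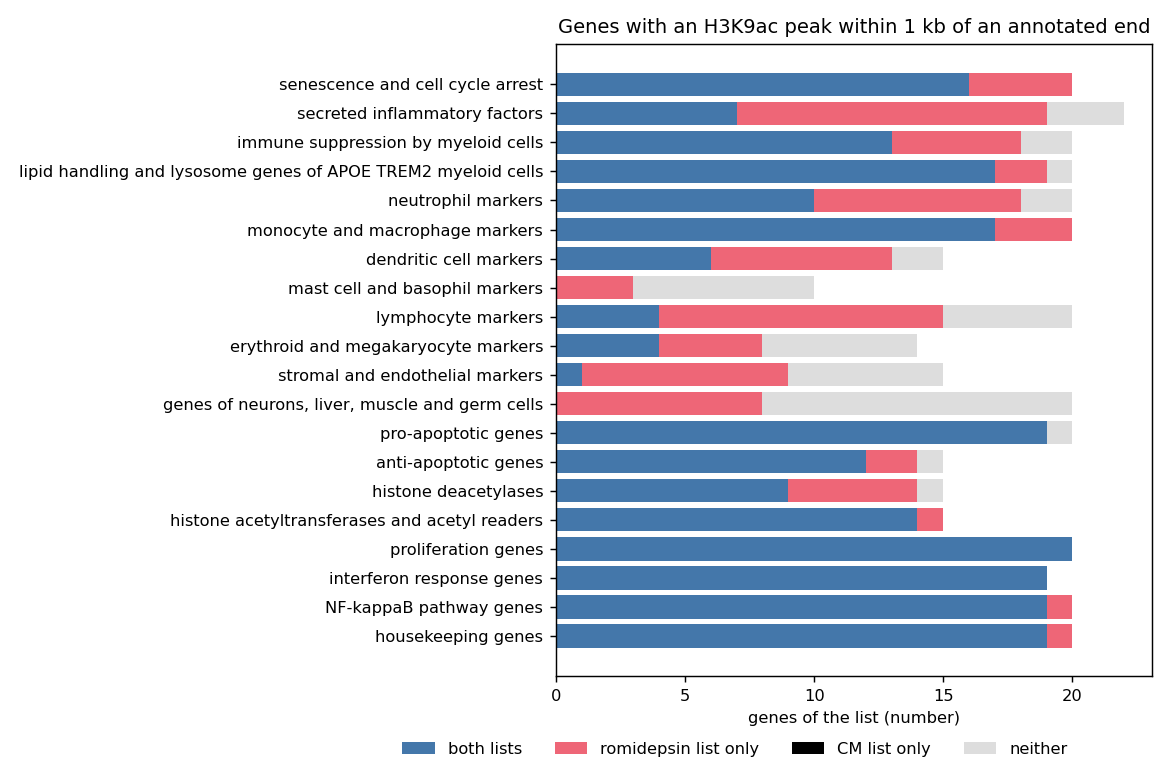
Number of genes in each of 20 fixed lists with a gene end peak in both lists, in the romidepsin list only, in the CM list only or in neither. The secreted inflammatory factors had 12 genes with a peak in the romidepsin list only, and the proliferation and interferon response genes had none.

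Genes of senescence and cell cycle arrest mostly had a peak in CM already. A peak was present at 16 of 20 genes in CM (percentile 99.8 among random lists) and at 20 of 20 with romidepsin. Such a CM percentile was not particular to this list: it was 100 for proliferation, interferon response, NF-kappaB pathway and housekeeping genes, 99.99 for pro-apoptotic and 99.9 for acetyltransferase and reader genes. Cdkn1a, which encodes the cell cycle inhibitor p21, had a CM peak of 709 bp (fold 4.19) and a romidepsin peak of 11163 bp (fold 4.24). Cdkn2a, which encodes p16 and p19ARF, had peaks of 374 bp (fold 4.30) and 1842 bp (fold 4.45). Both lay at the gene end at position 89294619 of chromosome 4. Start sites inside the gene were not examined, so these peaks do not show H3K9ac at the start of p16. Hmga1 had the highest romidepsin fold of the genes with a peak in both (4.68, in a peak that also reached AI413582). Among genes with a peak in romidepsin only, Cdkn2b, which encodes p15, had the highest fold (chromosome 4, 89309695 to 89311941, fold 4.14).

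Secreted inflammatory factors, which senescent cells can release, had a peak at 7 of 22 genes in CM (percentile 9.68) and at 19 of 22 with romidepsin (percentile 99.5). The 7 genes were Tnf, Cxcl2, Ccl3, Ccl4, Tgfb1, Vegfa and Osm. Ccl3 and Ccl4 shared 1 peak in each list, and the peaks at Tgfb1 also reached B9d2 and, with romidepsin, Tmem91. Tnf had a fold of 5.37 in CM and 4.68 with romidepsin. The 12 genes with a peak in the romidepsin list only were the interleukin genes Il1a, Il1b and Il6, the chemokine genes Cxcl1, Cxcl3, Cxcl10, Ccl2 and Ccl5, the growth factor genes Csf2 and Csf3, and the matrix protease genes Mmp9 and Mmp13. Mmp9 had the highest fold of these (chromosome 2, 164938268 to 164944260, 5993 bp, fold 3.76). The peaks at Il1a and Csf3 also reached Ckap2l and Med24. With equal numbers of strongest peaks the counts were 7 in CM and 13 with romidepsin. Il1a, Il1b, Il6, Cxcl3, Cxcl10, Csf3 and Mmp9 were then in the romidepsin list only. Cxcl2, which had a peak in the full romidepsin list, was in the CM list only.

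Genes of immune suppression by myeloid cells had a peak at 13 of 20 genes in CM (percentile 85.5) and at 18 of 20 with romidepsin. Arg1 and Nos2, which encode the arginine-consuming enzymes of suppressive myeloid cells, had a peak with romidepsin only (Arg1 at chromosome 10, 24928152 to 24929779, fold 2.85; Nos2 at chromosome 11, 78919714 to 78926464, fold 3.54), as did Ido1, Il10 and Olr1. Among equal numbers of strongest peaks the counts were 13 in CM and 14 with romidepsin. Nos2 and Il10 were then in the romidepsin list only, and Wfdc17, which had a peak in the full romidepsin list, in the CM list only. Il4ra had a fold of 6.31 in CM and 4.60 with romidepsin. Lipid handling and lysosome genes of APOE and TREM2 myeloid cells had a peak at 17 of 20 genes in CM (percentile 99.8) and at 19 of 20 with romidepsin. Apoe, an apolipoprotein gene, had a CM peak of 760 bp (fold 3.53) in its gene end window. That peak (chromosome 7, 19694821 to 19695580, −log10 q 1.52) lay wholly outside the gene, which begins at 19696244. The romidepsin peak of 14750 bp (fold 3.64) covered Apoe and also reached Apoc1 and Tomm40. Trem2, a lipid-sensing receptor gene of myeloid cells, had peaks of 2680 bp (fold 4.98) and 7444 bp (fold 3.47). Tyrobp, which encodes the adaptor of TREM2, had a fold of 6.51 in CM and 4.32 with romidepsin, where the peak also reached Hcst and Nfkbid. These folds came from different peaks that did not overlap (chromosome 7, 30412950 to 30414784 in CM and 30416189 to 30431789 with romidepsin). Cd63 (fold 3.80, peak shared with Rdh5) and Spp1 had a gene end peak with romidepsin only, although Cd63 had a CM peak elsewhere in the gene.

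Monocyte and macrophage markers had a peak at 17 of 20 genes in CM (percentile 99.9) and at 20 of 20 with romidepsin, where Mrc1 (fold 3.01), C1qa (peak shared with C1qc) and Marco had a peak in addition. The counts were 17 in CM and 16 with romidepsin among equal numbers of strongest peaks, with F13a1 in the CM list only. Klf4, a monocyte transcription factor, had a fold of 6.02 in CM and 4.88 with romidepsin. Neutrophil markers had a peak at 10 of 20 genes in CM (percentile 67.6) and at 18 of 20 with romidepsin (percentile 99.8). Gfi1, a transcription factor of neutrophil differentiation, had a fold of 4.32 in CM and 4.79 with romidepsin, and S100a8, which encodes a calprotectin subunit, had 3.82 and 3.22. The 8 neutrophil genes with a peak in romidepsin only were Mpo, the myeloperoxidase gene (fold 3.46), Ctsg, Camp, Ltf, Ngp, Fcnb, S100a9 and Ly6g. With equal numbers of strongest peaks the neutrophil counts were 10 in CM and 9 with romidepsin. Mpo and Ctsg were then in the romidepsin list only, and S100a8, Cebpe and Chil3 in the CM list only. S100a8, Cebpe, Chil3 and F13a1 each had a peak in the full romidepsin list, and only that list was cut.

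Markers of other cell types that a bone marrow culture could hold had a peak at more genes in the full romidepsin list than in CM, and most of this difference was not seen among equal numbers of strongest peaks. There the counts in CM and with romidepsin were 4 and 3 for lymphocyte, 6 and 7 for dendritic cell, 0 and 1 for mast cell and basophil, 4 and 6 for erythroid and megakaryocyte, and 1 and 3 for stromal and endothelial markers, and 0 and 3 for genes of neurons, liver, muscle and germ cells. In the full lists, dendritic cell markers had a peak at 6 of 15 genes in CM and 13 of 15 with romidepsin. Bcl11a had a fold of 4.90 in CM and 4.30 with romidepsin, and Zbtb46 had a gene end peak with romidepsin only (fold 3.86, shared with Abhd16b and Tpd52l2) and a CM peak elsewhere in the gene. Lymphocyte markers had a peak at 4 of 20 genes in CM (percentile 0.205) and 15 of 20 with romidepsin. The CM peak at Cd79a, which encodes a B cell receptor subunit, lay also at Arhgef1, and Eomes had a romidepsin peak only (fold 3.61). Mast cell and basophil markers had a peak at 0 of 10 genes in CM and 3 of 10 with romidepsin, with Gata2 the strongest (fold 3.62). Erythroid and megakaryocyte markers had a peak at 4 of 14 and 8 of 14 genes, and at 7 and 8 with windows of 2.5 kb. Tal1 had a peak in both, and the romidepsin peak at Gp1ba (fold 4.42) also reached Eno3, Pfn1, Rnf167 and Slc25a11. Stromal and endothelial markers had a peak at 1 of 15 genes in CM, namely Kdr, and at 9 of 15 with romidepsin, including the collagen gene Col1a1 (fold 3.79). The stromal and endothelial counts were 2 and 10 with windows of 2.5 kb. Genes of neurons, liver, muscle and germ cells had a peak at 0 of 20 genes in CM and 8 of 20 with romidepsin (percentile 0.8 among random lists), including the germ cell gene Dazl (fold 3.74). Neurod1, a neuronal transcription factor gene, had no gene end peak in either list and a romidepsin peak within the gene. Over whole gene spans, the counts in CM and with romidepsin were 8 and 13 for dendritic cell and 6 and 15 for lymphocyte markers. They were 1 and 3 for mast cell and basophil, 5 and 8 for erythroid and megakaryocyte, and 3 and 10 for stromal and endothelial markers. For genes of neurons, liver, muscle and germ cells they were 1 and 12.

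Apoptosis genes mostly had a peak in both lists. Pro-apoptotic genes had one at 19 of 20 genes in CM and 19 of 20 with romidepsin, with Hrk in neither. Bcl2l11, which encodes the BH3-only protein BIM, had a fold of 5.88 in CM and 4.39 with romidepsin, in peaks that also reached Acoxl, and Cycs, the cytochrome c gene, had 6.11 and 4.83. Anti-apoptotic genes had a peak at 12 of 15 and 14 of 15 genes. Mcl1 had a fold of 7.35 in CM and 4.20 with romidepsin, and Birc6 had 6.96 and 4.55. Bcl2l1, which encodes BCL-XL, had a gene end peak with romidepsin only (fold 3.93) and a CM peak elsewhere in the gene.

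Histone deacetylase genes had a peak at 9 of 15 genes in CM and 14 of 15 with romidepsin. Hdac4, Hdac6, Hdac7 (peak shared with Slc48a1), Hdac8 and Hdac11 (fold 3.59) had a gene end peak with romidepsin only, and Hdac4 and Hdac7 had a CM peak elsewhere in the gene. Hdac3 had a fold of 4.84 in CM and 4.80 with romidepsin, in peaks shared with Rell2 and, with romidepsin, Fchsd1. Histone acetyltransferase and acetyl reader genes had a peak at 14 of 15 and 15 of 15 genes, with a gene end peak at Brd3 in the romidepsin list only (fold 3.19) and a CM peak elsewhere in that gene, and Brd2 at 7.32 in CM and 4.50 with romidepsin in peaks shared with H2-DMa. Proliferation genes had a peak at 20 of 20 genes in both lists, with Mcm5 at 4.77 in CM and 4.34 with romidepsin. Interferon response genes had a peak at 19 of 19 genes in both lists, with the DNA sensor gene Cgas at 6.52 and 4.13 in peaks shared with Mto1. NF-kappaB pathway genes had a peak at 19 of 20 and 20 of 20 genes, with Irak3 at 6.49 and 4.40. Nfkb2 had a gene end peak in the romidepsin list only (fold 4.10) and a CM peak elsewhere in the gene. Housekeeping genes had a peak at 19 of 20 and 20 of 20 genes. Actb had a fold of 6.82 in CM and 4.12 with romidepsin, where the peak also reached Fbxl18, B2m had 6.63 and 5.00, and Ywhaz had a gene end peak with romidepsin only (fold 2.42) and a CM peak elsewhere in the gene. Among equal numbers of strongest peaks, the counts in CM and with romidepsin were 9 and 10 for histone deacetylase genes, with Hdac11 in the romidepsin list only, 14 and 14 for acetyltransferase and reader genes, 20 and 19 for proliferation, 19 and 17 for interferon response, 19 and 18 for NF-kappaB pathway and 19 and 17 for housekeeping genes. They were 16 and 17 for senescence and cell cycle arrest, 17 and 19 for lipid handling and lysosome, 19 and 19 for pro-apoptotic and 12 and 14 for anti-apoptotic genes. Genes in the CM list only in this setting included Tlr7, Ikbkg, Irak1, Hprt and Pgk1 on chromosome X. All of these had a peak in the full romidepsin list.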

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

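The alternatives were fixed before the data were examined, except whole gene spans. The ratio of peak numbers (6.29) reversed at a fold of at least 5 (0.0109), as did that of covered sequence (0.0203, from 8.70). It moved to 1.69 at a fold of at least 3, 1.92 and 2.69 at −log10 q of at least 5 and 10, and 4.05 with peaks closer than 1 kb merged, and covered sequence moved to 5.34, 5.62 and 4.50 at those fold and q thresholds. At −log10 q of at least 5, the shared share was 95.8% of CM and 47.9% of romidepsin peaks, the gene end share 87.0% and 69.7%, and genes with a peak in CM only numbered 219. With equal numbers of strongest peaks the shared shares were 90.2% and 71.8%, the romidepsin gene end share 58.6%, and genes with a peak in romidepsin only and CM only numbered 1040 and 565. The shared shares were 99.81% and 1.34% with 50% of a peak covered, and 99.76% and 6.89% with the peak centre inside. Gene end shares were 65.9% and 23.2% with windows of 2.5 kb, and 57.0% and 14.7% with 500 bp, where 3 genes had a peak in CM only, and 2 did over whole gene spans. The cause of these movements was not tested beyond the thresholds themselves. The ratio of genes with a peak stayed above 1 in all 5 alternatives run, from 1.04 to 1.56. These did not include the fold thresholds, where the ratio of peak numbers reversed. At a fold of at least 5, only 91 romidepsin peaks were left against 8320 CM peaks. The gene ratio was thus not shown to hold there. Counts of genes per list changed by over 1.5 times, or from 0, in 6 of the 20 romidepsin values with equal numbers of peaks. The 20 CM values could not change there, since the CM list was kept whole. Such changes were seen in 2 of 40 values with windows of 2.5 kb and 3 of 40 over whole gene spans, the last by 1 or 2 genes each. Percentiles changed by over 10 points in 5 of 40 values without matching. No paired analysis was possible because each condition had 1 immunoprecipitated library. The alternatives using the most upstream start site and CpG content were not run, since strand and sequence were not used here. Unknown depth limits each comparison of the 2 lists.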

Other observations

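All tests in this part were chosen after the counts had been seen. Of the 966 protein-coding genes on chromosome X, 237 (24.5%) had a gene end peak in CM and 343 (35.5%) with romidepsin, against 50.5% and 65.9% of autosomal genes. At genes with a peak in both lists, the median fold on chromosome X was 0.727 times the autosomal one in CM and 0.743 times with romidepsin. With equal numbers of strongest peaks, 237 genes on chromosome X had a peak in CM and 14 with romidepsin, while autosomal genes numbered 10441 and 11142. Only the romidepsin list was cut in this setting, and folds on chromosome X were low in both full lists. The count of 14 therefore does not show a loss of H3K9ac on chromosome X. Listed genes on chromosome X with a CM peak but no romidepsin peak among the strongest were Tlr7, Ikbkg (peaks shared with Fam3a), Irak1, Hprt and Pgk1. Each of them had a peak in the full romidepsin list. Chromosome Y carried 3 peaks in CM, at Eif2s3y, Uty and Ddx3y, and 15 with romidepsin, with Kdm5d added.

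Several of the highest folds lay in 2 clusters of peaks. A region of chromosome 6 from 47672354 to 47773090 held 12 CM peaks at a median spacing of 4.37 kb and 2 of the 10 highest romidepsin folds, up to 7.22. A region of chromosome 8 from 19784391 to 20554145 held 10 CM peaks, among them 4 of the 10 highest CM folds, up to 14.6, against at most 4.76 with romidepsin.

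The first pattern weighed was the larger number of romidepsin peaks. A deeper romidepsin library is a candidate explanation. Of the 4884 romidepsin peaks with a fold of 4 or more, 95.8% overlapped a CM peak. The share fell to 15.8% at a fold of 3 to 3.5 and 0.106% under 2.5. Acetylation gained at weaker sites could give the same fall, so these shares do not favour depth. Estimated background pileup was 4.05 with romidepsin and 0.6 in CM, and the estimate ran high in simulated lists, most so at low background. Acetylation at more sites after romidepsin stays open as well, since 203 strong romidepsin peaks had no CM peak, of which 23.6% lay at gene ends. The 2 cannot be told apart, because 1 library of unknown depth stands for each condition.

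The second pattern was the number of secreted inflammatory factors with a peak in the romidepsin list only (12 genes). This list and the neutrophil list were picked from 20 after their counts were seen. A limit of 99.875 that allows for 20 lists therefore replaced 97.5 after the percentiles were known. All percentiles of the secreted inflammatory factors given for this pattern lie above 97.5. Random genes without a CM peak had a romidepsin peak less often (percentile 99.99 among all such genes and 99.965 without receptor families and unnamed genes), which argues against a gain that any such gene shows. Random genes were drawn singly, whereas some listed genes are neighbours, such as Il1a and Il1b on chromosome 2. Cxcl1 and Cxcl3 on chromosome 5 also lie close together, so the percentiles may overstate the excess. Weak peaks under the detection limit of the CM library may still account for it: among genes with romidepsin peaks of like fold the percentile was 99.365, short of the limit, while it was 99.92 with fold and length matched and 99.995 with length alone matched, both past it. The fold-matched excess was not particular to inflammatory genes. The fold-matched percentile was 99.335 for stromal and endothelial markers and 99.965 for genes of neurons, liver, muscle and germ cells. Among all genes without a CM peak, these lists had lower percentiles of 94.06 and 72.71. There, lists above 97.5 but under the limit were senescence (99.455), neutrophil (99.87), monocyte (97.82), dendritic cell (99.38), lymphocyte (99.39) and histone deacetylase (99.155).

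The third pattern was the number of neutrophil markers with a peak in the romidepsin list only (8 genes). Against random genes without a CM peak the percentile was 99.87 among all such genes and 99.665 without receptor families and unnamed genes. Both lay above 97.5 and under the limit for 20 lists, the former by little, so a gain that any such gene shows is not excluded. Against genes with romidepsin peaks of like fold it was 23.9, with 8 genes observed and a median of 9 at random, and with the other 2 matchings it was 39.04 and 46.125. Weak peaks under the detection limit of the CM library are a candidate explanation for these genes, and no biological explanation could be separated from it.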
